A study of Homo sapiens with 6 samples.

How the data were processed

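Messenger RNA sequencing was compared across 6 libraries of human embryonic stem cells, in which DDX18, a DEAD-box RNA helicase of the nucleolus, was depleted with short hairpin RNAs. The cells were the established lines H9 and HES2, grown on inactivated mouse embryonic fibroblast feeders and collected on day 4 after viral infection. Each line contributed 1 library with a control hairpin against luciferase (shLuc) and 1 library with each of 2 hairpins against DDX18 (shDDX18#1 and shDDX18#3). Replicate 1 of each arm is H9 and replicate 2 is HES2. The labels do not say that the libraries of a line came from separate cultures, so the p-values measure only the spread between these 6 samples.

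Libraries were made with a TruSeq RNA kit, which does not keep the strand of a read, and per the submitters' processing notes reads were handled with Bowtie2 2.3.4.3, SAMtools 1.9, HTSeq 0.11.2 and edgeR 3.26.8 against hg19, without the part each tool played being stated. The authors deposited 1 table of 17929 genes with a normalized signal per library, a log2 fold change and mean log2 abundance, a likelihood ratio statistic as a score, a p-value and a false discovery rate. The authors' table gives these test values for knockdown against shLuc, and the design behind them is not stated. Tested on the table, the deposited signal is counts per 1e+06 reads of an effective library size (CPM): every value was a whole number of reads, within a tolerance of 0.001, once divided by the value of 1 read in its library. The recovered totals were 3647530, 2668179 and 3178058 reads for H9 shLuc, shDDX18#1 and shDDX18#3, and 4271741, 2966308 and 3391529 reads for HES2 in the same order. A single read is therefore worth between 0.224 and 0.408 CPM, and a floor of 3 reads lies between 0.671 and 1.23 CPM. These floors, and the counting intervals given for ratios, cover counting error only. The authors' log2 fold changes and false discovery rates were compared with the values computed here, and their likelihood ratio score and mean abundance were not used here. Gene positions on hg19 were not used here, and gene types, exon lengths and gene order came from a GENCODE annotation on GRCh38. Symbols came from the deposited table for 15532 genes and from a gene name table for 600, and 1797 genes have no symbol.

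Comparisons were fitted on log2(value + 1), and every fold change below is on that scale. Genes with at least 1 CPM in at least 2 libraries were tested, which kept 17768 and left out 161. The test was limma 3.58.1 in R 4.3.3 with an intensity trend in the prior variance (limma-trend) and Benjamini-Hochberg adjustment, with genes called at an adjusted p under 0.05. The main model compared the 4 knockdown libraries with the 2 shLuc libraries with cell line as a block. Further models compared each hairpin with shLuc, the hairpins with each other, the knockdown effect in HES2 with that in H9 (an interaction term), and HES2 with H9 with the arm as a block. Because each arm has 1 library per line, all 6 libraries share 1 estimate of spread.

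In addition, 36 gene lists were tested with camera from limma at its preset correlation of 0.01, adjusted over the lists, for lists with at least 5 measured members. Members called over all genes were counted, and calls were also counted adjusted over the list alone. Camera with a correlation estimated from the residuals and fry were run beside it. With an estimated correlation camera takes its p from the residual degrees of freedom, 3 in the main model and 2 in the others. A list can hardly pass on so few, whatever its correlation. Cholesterol synthesis, with an estimate of 0.0036, below the preset, had a camera adjusted p = 0.336 in the main comparison. A miss there thus does not show that correlation between genes accounts for a call. The comparisons, the lists, the alternatives listed in the closing section and the rule for naming genes were chosen before the data were examined. The rule named DDX18, the 12 largest rises and the 12 largest falls among called genes with a symbol, a mean of at least 3 CPM and the same direction in all 4 knockdown libraries. It added up to 4 members with the smallest p of each called list, up to 2 of each other list, and the 5 largest in each direction in the other comparisons, or the 5 with the smallest p where fewer than 2 passed. SOX2, NANOG, POU5F1, CDKN1A, MDM2, NPM1 and NCL were added after their values had been seen, as were the genes named in the closing section. The values of 4 genes that the rule names are not reported here.

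The alternatives were pseudocounts of 0.25 and 4, no filter or a filter of 5 CPM, 3 other scalings, limma without the trend or with a robust prior, no block, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, a fold threshold, and leaving out each library in turn. Where a library left out leaves an arm with 1 library, that library is assumed to vary like the others. With cell line as a block, leaving out the shLuc library of a line leaves the main comparison to be estimated from the other line alone. Knockdown effects given without H9 shLuc are thus effects in HES2, and those without HES2 shLuc are effects in H9. The pairing of libraries by line was checked from the values: the difference between HES2 and H9 correlated across genes between shLuc and shDDX18#1 with r of 0.363, between shLuc and shDDX18#3 with r of 0.454 and between the hairpins with r of 0.654.

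The pipeline was tested on simulated data with the same libraries and 100 genes changed at each size. At a log2 change of 1 the main comparison recovered 54 of 100 genes and at a log2 change of 2 it recovered 92, with 12 false calls among 158. The test of the difference between lines recovered 2 of 100 at a change of 1 and 42 of 100 at a change of 2, so it misses most differences of the smaller size. Camera called the changed list in each of the 6 simulated comparisons and called 1 of 35 unchanged lists in HES2 against H9 and 0 of 35 in the main comparison. Apart from the changed genes, every simulated library had the same mean per gene, with the spread of the model by arm. Differences between hairpins, which add to the spread in the main model, were not simulated. The data also hold far more called genes, 2819 in the main comparison, so recovery there can differ. The simulated genes varied independently and the unchanged lists were drawn at random. Real lists are correlated, with an estimate of 0.88 for G2 and M phase in the main comparison. The simulation therefore cannot show how often camera at its preset correlation calls such lists falsely.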

Results

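DDX18 depletion was compared with a luciferase control in H9 and HES2 cells to address what the helicase does for the identity of human embryonic stem cells. Levels are given as the deposited normalized signal in counts per 1e+06 reads of effective library size (CPM), as mean ± SD over the 4 knockdown libraries and the 2 shLuc libraries, fold changes on the log2(value + 1) scale, and adjusted p-values from limma for genes and from camera for gene lists.

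DDX18 (ENSG00000088205) itself stood at 153 CPM in H9 shLuc, 19.2 in H9 shDDX18#1 and 47.3 in H9 shDDX18#3. In HES2 the values were 161 in shLuc, 39.3 in shDDX18#1 and 60.4 in shDDX18#3. The transcript remaining was 12.6% and 31.0% of the line's own shLuc in H9 and 24.5% and 37.6% in HES2, for shDDX18#1 and shDDX18#3 respectively. Across hairpins DDX18 fell from 157 ± 5.44 (n = 2) to 41.6 ± 17.3 (n = 4), a log2 fold change of -2.0 with SE 0.35 (limma adjusted p = 0.0109), and the authors' deposited table gives -1.94. The fall was present in 4 of 4 knockdown libraries. The call was not kept when either shLuc library was left out, where the effect is estimated from the other line alone.

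**Figure D1:**
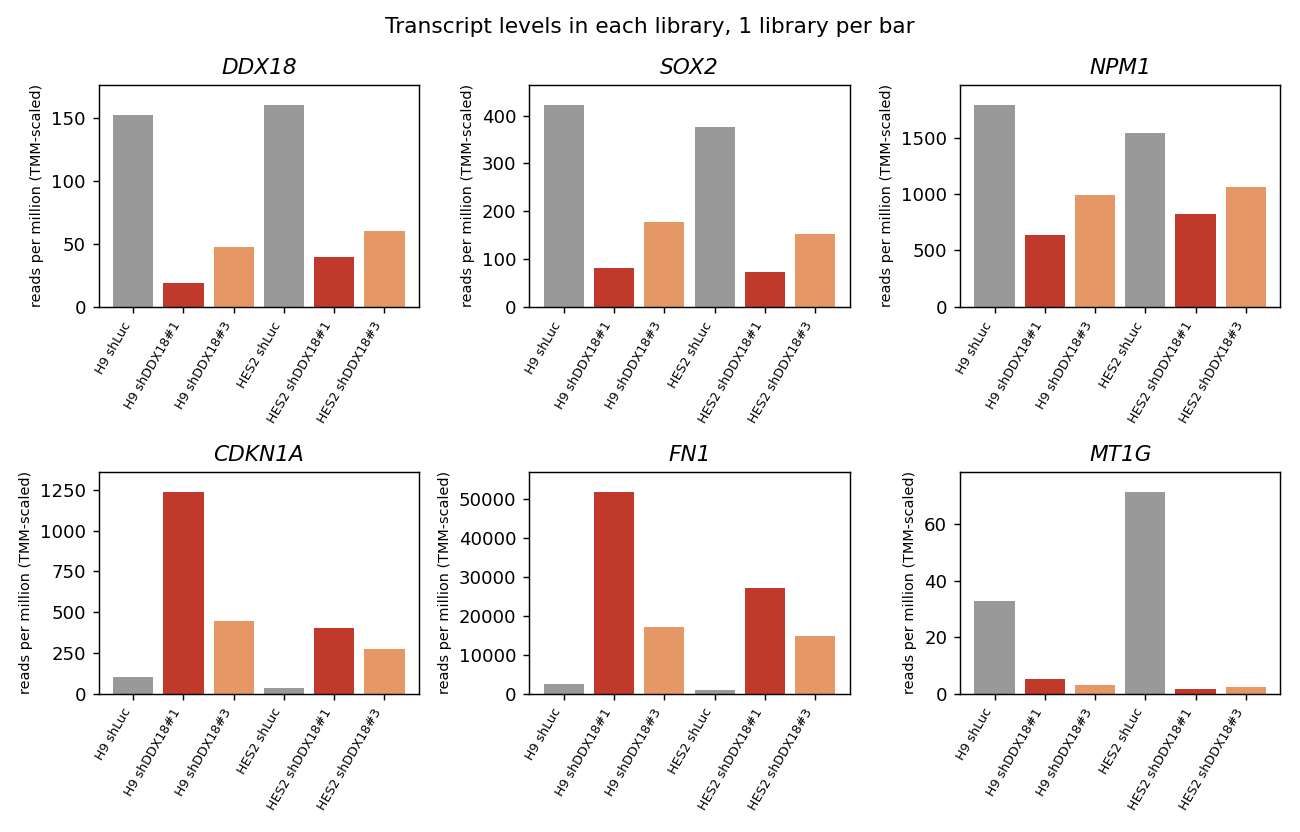
CPM (y axis, linear, from 0) of DDX18, SOX2, NPM1, CDKN1A, FN1 and MT1G in each of the 6 libraries (x axis), with 1 bar per library, gray for shLuc and red and orange for the hairpins. DDX18 lies between 19.2 and 60.4 in the knockdown libraries against 153 and 161 in shLuc.

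In the knockdown libraries transcripts of the pluripotent state, of ribosome production and of cell division fell, and those of p53 targets, mesenchymal genes, several lineages and fibroblast and feeder markers rose. These are calls of camera at its preset correlation, which 21 of 36 lists passed. With an estimated correlation 0 lists passed, in a test on 3 residual degrees of freedom that could hardly call any. In limma 1706 genes rose and 1113 fell in the knockdown libraries, of which 1217 and 461 by at least 2-fold. Of these 2819 genes, 2792 are also among the 4102 with a false discovery rate under 0.05 in the authors' deposited table, and the fold changes there and here correlated across genes with r of 0.93. Protein-coding genes made up 1534 of the rises and 1013 of the falls, and long intergenic RNAs 30 and 23. Of 125 called genes named by the rule or added to it, 48 passed without H9 shLuc and 23 without HES2 shLuc. The number of calls depends on single libraries: without HES2 shDDX18#1 771 genes rose and 243 fell, and without HES2 shDDX18#3 1064 rose and 488 fell. Fewer genes still were called without H9 shLuc or HES2 shLuc, where the effect is estimated from the other line alone.

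Among the 12 largest rises was ANKRD1, which encodes a cardiac and stretch-responsive nuclear protein and went from 12 ± 7.75 (n = 2) to 261 ± 125 (n = 4), a log2 fold change of 4.34 with SE 0.48 (adjusted p = 0.00284), with 3.59 and 2.76 in H9 and 5.83 and 5.19 in HES2. MARCH4, a membrane ubiquitin ligase, rose by 4.23, and NPPB, the natriuretic peptide B precursor, by 4.10. ACTA2, smooth muscle actin, rose by 4.08 from 11.4 to 168 CPM, and its antisense transcript ACTA2-AS1 by 4.22. ACTA2, ACTA2-AS1 and FAS overlap on the chromosome and the kit keeps no strand, so how their reads divide is uncertain. The cytokine IL11 rose from 2.34 ± 0.173 (n = 2) to 47.9 ± 6.58 (n = 4), a log2 fold change of 3.86 with SE 0.21 (adjusted p = 0.000619). The remaining rises of the 12 were the growth factor binding protein IGFBP3 (4.07), the Golgi protein GASK1B (3.90) and the matrix genes COL3A1 (3.98), FN1 (3.95), COL1A1 (3.94) and COL6A3 (3.92). Of the 12 largest falls, 3 were metallothioneins, small metal-binding proteins: MT1G fell from 52.1 ± 27.5 (n = 2) to 3.02 ± 1.62 (n = 4), a log2 fold change of -3.70 with SE 0.44 (adjusted p = 0.00313), MT1H changed by -3.07 and MT1E by -2.49. MT1E was at -1.47 and -1.41 in H9 and -3.09 and -4.02 in HES2, and without HES2 shLuc it stood at -1.44 (adjusted p = 0.142). The neural transcription factor genes FOXB1 (-3.14) and HES3 (-3.05), the phospholipase PLA2G3 (-2.93) and the muscle actinin ACTN3 (-2.78) also fell. So did CNMD, which encodes chondromodulin (-2.57), WDR76, a ubiquitin ligase adaptor (-2.45), ALDOC, a glycolytic aldolase (-2.43), and LCK, a lymphoid kinase (-2.33). Among these 24 genes, 16 passed without H9 shLuc and 9 without HES2 shLuc, while 6 passed in every alternative tried. FOXB1 stood at -2.03 without H9 shLuc (adjusted p = 0.106), and HES3 had too few reads to be tested without a shLuc library.

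Genes of the pluripotent state fell as a group. DNMT3B, the de novo DNA methyltransferase of early embryos, went from 1438 ± 126 (n = 2) to 379 ± 88.3 (n = 4), a log2 fold change of -1.95 with SE 0.22 (adjusted p = 0.0029). SOX2, a core pluripotency factor, fell by 1.82 (adjusted p = 0.0154) and NANOG by 1.38 (adjusted p = 0.029), and PRDM14 (-2.13), TERF1 (-2.14) and TRIM71 (-1.16) fell with them. Of 33 measured pluripotency genes 0 rose, 19 fell and 14 did neither, with 2 rises and 28 falls adjusted over the list alone. The list's median was -1.34 (camera adjusted p = 1.66e-11), against an adjusted p = 0.356 with an estimated correlation. POU5F1 cannot be read from these values, since its gene held 1.66 and 3.58 CPM in shLuc while the summed copies POU5F1B, POU5F1P3 and POU5F1P4 held 267 and 263. Naive pluripotency genes as a list did not pass, with 2 of 9 rising and 1 falling, also adjusted over the list alone, and a median of 0.68 (camera adjusted p = 0.232), although KLF5 (1.68) and TBX3 (1.95) rose. KLF5 did not pass without H9 shLuc (adjusted p = 0.101) or without HES2 shLuc (0.0785). TBX3 was 1.03 without HES2 shLuc (0.173) and did not pass without the trend (0.0588) or the block (0.0604). The naive list passed without H9 shLuc (median 1.28, camera adjusted p = 0.021). The 4 members named by their p, DNMT3B, PRDM14, TERF1 and TRIM71, passed in 6 libraries but had adjusted p between 0.0558 and 0.075 without HES2 shLuc, and 3 of the 4 also missed the threshold without H9 shLuc, where DNMT3B had 0.0368. SOX2 had 0.135 without H9 shLuc and 0.141 without HES2 shLuc.

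Transcripts of several lineages rose while the pluripotency genes fell. HNF4A, a liver and endoderm transcription factor, rose from 3.39 ± 2.26 (n = 2) to 48.6 ± 23.3 (n = 4), a log2 fold change of 3.47 with SE 0.43 (adjusted p = 0.00378), beside APOA2 (2.97), CXCR4 (2.68) and GATA6 (1.99). Of 22 endoderm genes 11 rose and 1 fell (14 and 1 adjusted over the list alone), with a median of 1.64 (camera adjusted p = 7.73e-07) and an adjusted p = 0.390 with an estimated correlation. In the trophoblast and amnion list 7 of 19 rose and 0 fell (8 and 0 adjusted over the list alone), among them GATA3 (3.19), EPAS1 (2.92) and SLC40A1 (2.25). That list's median was 1.09 (camera adjusted p = 9.68e-05), with an adjusted p = 0.336 with an estimated correlation, and 1.66 without H9 shLuc. Mesoderm genes went both ways, 10 of 31 rising and 4 falling (12 and 5 adjusted over the list alone), with SNAI2 (2.87), FOXC2 (2.78), TWIST1 (2.61) and MYL7 (2.24) up. The mesoderm median was 1.12 (camera adjusted p = 0.00515), with an adjusted p = 0.390 with an estimated correlation, and without HES2 shLuc the median was 0.42 (camera adjusted p = 0.0611). For neural ectoderm 3 of 18 rose and 0 fell (11 and 1 adjusted over the list alone), namely CDH2 (1.65), OTX2 (1.28) and PAX6 (2.25). In the main fit DCX at -1.06 did not pass (adjusted p = 0.0548). It passed as a fall without H9 shDDX18#3 (adjusted p = 0.0443), at a pseudocount of 4, after quantile normalization, without the trend and with edgeR. This list's median was 1.20 (camera adjusted p = 0.00203), with an adjusted p = 0.336 with an estimated correlation, and 0.80 without H9 shLuc. HOX genes, which pattern the body axis, had 5 of 18 rising and 0 falling (13 and 0 adjusted over the list alone), with a median of 1.25 (camera adjusted p = 3.35e-06) and an adjusted p = 0.336 with an estimated correlation. HOXB3 (2.24) and HOXB2 (2.52) passed, though not without HES2 shLuc (1.26 with adjusted p = 0.238 for HOXB3 and 0.286 for HOXB2), and HOXA11 (1.65, adjusted p = 0.0699) and HOXB6 (1.22, adjusted p = 0.19) did not. HOXA11 stood at 0.81 without H9 shLuc and 2.50 without HES2 shLuc. It passed at a pseudocount of 0.25 (2.56), with edgeR (3.68) and with DESeq2 (3.83). HOXB6 stood at 2.12 without H9 shLuc and 0.32 without HES2 shLuc. It was at -0.58 in H9 shDDX18#1 and passed without that library (1.73). Neural crest genes as a list did not pass (6 of 16 rose, 3 fell, 7 and 3 adjusted over the list alone, median 0.62, camera adjusted p = 0.194), except without H9 shLuc (camera adjusted p = 0.0443). Fibroblast and feeder markers rose in the same libraries, from 0.414% to 4.58% and 1.97% of reads in H9 and from 0.185% to 0.683% and 0.62% in HES2, for shDDX18#1 and shDDX18#3.

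Matrix and mesenchymal transcripts rose. FN1, fibronectin, rose from 1725 ± 989 (n = 2) to 27717 ± 16952 (n = 4), a log2 fold change of 3.95 with SE 0.48 (adjusted p = 0.00347), and held 4.76% of all reads in H9 shDDX18#1 against 0.24% in H9 shLuc. Of 17 genes of the epithelial to mesenchymal transition 13 rose and 0 fell (14 and 0 adjusted over the list alone), including COL5A1 (3.20), the repressor ZEB1 (3.13), the fibronectin receptor subunit ITGA5 (2.08) and SPARC (1.99). Their median was 2.24 (camera adjusted p = 8.02e-11), with an adjusted p = 0.336 with an estimated correlation. Fibroblast and feeder markers, of which 4 are also in the mesenchymal list, rose in 18 of 26 cases and fell in 0 (20 and 0 adjusted over the list alone). Their median was 2.28 (camera adjusted p = 4.54e-14), with an adjusted p = 0.336 with an estimated correlation, and CCN1 (1.48) was named with ACTA2 and COL1A1. By library the fibroblast median was 3.43 and 2.27 in H9 and 2.18 and 1.82 in HES2. Without HES2 shLuc the adjusted p was 0.0857 for FN1, 0.078 for COL6A3 and 0.0558 for IGFBP3 and GASK1B, and without H9 shLuc it was 0.0576 for COL6A3. Epithelial junction genes as a list did not pass (7 of 21 rose, 1 fell, the same adjusted over the list alone, median 0.12, camera adjusted p = 0.232), and the simple-epithelium keratins KRT19 (1.65) and KRT18 (1.38) rose.

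Lists of ribosome production moved down in camera at its preset correlation, and 0 of them passed with an estimated correlation. In each of these lists except ribosomal proteins, most genes were not called. Among the nucleolar proteins NPM1 fell by 0.94 (adjusted p = 0.0319) and NCL by 0.97 (adjusted p = 0.0291), and the RNA acetyltransferase NAT10 went from 167 ± 21.4 (n = 2) to 68.0 ± 21.3 (n = 4), a log2 fold change of -1.33 with SE 0.17 (adjusted p = 0.00408). Of 115 ribosome biogenesis genes 0 rose and 33 fell (0 and 51 adjusted over the list alone), with RRP1B (-0.83), NOP53 (-0.80) and TBL3 (-0.76) among them. The median was -0.48 (camera adjusted p = 9.95e-15), with an adjusted p = 0.418 with an estimated correlation. Messenger RNAs of cytosolic ribosomal proteins fell in 43 of 78 cases and rose in 0 (71 and 0 adjusted over the list alone), such as RPL10A (-0.98), RPS9 (-0.97), RPS3 (-0.91) and RPL29 (-0.73). Their median was -0.58 (camera adjusted p = 7.82e-20), with an adjusted p = 0.390 with an estimated correlation, and their share of reads went from 5.50% to 3.14% and 4.10% in H9 and from 5.61% to 3.22% and 3.79% in HES2. Host genes of small nucleolar RNAs, which guide ribosomal RNA modification, fell in 6 of 21 cases (13 adjusted over the list alone) and rose in 0, with a median of -0.64 (camera adjusted p = 5.60e-07) and an adjusted p = 0.356 with an estimated correlation. SNHG4 (-1.79), SNHG1 (-1.03), SNHG3 (-0.94) and SNHG5 (-0.92) were those named. The RNA polymerase I list also holds subunits shared with other RNA polymerases, such as POLR2L. It had 4 of 19 genes falling and 1 rising (5 and 1 adjusted over the list alone). Its median was -0.36 (camera adjusted p = 0.000163), with an adjusted p = 0.451 with an estimated correlation. UBTF (-0.88), POLR1B (-0.86) and POLR1E (-0.75) fell and POLR2L (0.55) rose. Of 18 alternatives POLR1E and POLR2L each missed the threshold in 6, NPM1 and NCL each in 5, POLR1B in 4 and UBTF in 3. RPL10A did not pass without H9 shLuc (adjusted p = 0.116) or without HES2 shLuc (0.16), and NAT10 did not pass without H9 shLuc (0.0616).

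Cell-cycle transcripts fell and p53 targets rose. E2F1, which drives entry into S phase, went from 57.7 ± 11.1 (n = 2) to 16.4 ± 5.20 (n = 4), a log2 fold change of -1.79 with SE 0.22 (adjusted p = 0.00354), and E2F2 (-1.93), MCM6 (-1.41) and CCNE1 (-1.23) fell too. Of 40 S phase genes 27 fell and 0 rose (35 and 0 adjusted over the list alone), with a median of -1.18 (camera adjusted p = 1.62e-14) and an adjusted p = 0.390 with an estimated correlation. Of 38 genes of G2 and M phase 13 fell and 0 rose (25 and 0 adjusted over the list alone), among them the cyclins CCNA2 (-1.30) and CCNB2 (-1.01), the kinase BUB1 (-1.25) and KIF20A (-1.24). This list's median was -0.85 (camera adjusted p = 2.23e-10), with an adjusted p = 0.451 with an estimated correlation. CDKN1A, the p21 inhibitor of the cell cycle, rose from 67.5 ± 49.0 (n = 2) to 591 ± 437 (n = 4), a log2 fold change of 3.08 (adjusted p = 0.00313), and MDM2, the ubiquitin ligase of p53, by 2.03 (adjusted p = 0.00218). Of 40 p53 targets 27 rose and 0 fell (34 and 0 adjusted over the list alone), with FAS (3.06), BTG2 (2.61), ZMAT3 (2.16) and TP53I3 (2.15) named. Their median was 1.16 (camera adjusted p = 2.19e-18), with an adjusted p = 0.336 with an estimated correlation, and the 4 named targets passed without either shLuc library. Apoptosis effectors, of which 5 are also p53 targets, rose in 8 of 28 cases and fell in 1 (10 and 3 adjusted over the list alone), with APAF1 (1.05), TNFRSF10A (1.39) and TNFRSF10B (0.95) beside FAS. The apoptosis median was 0.31 (camera adjusted p = 0.0275), with an adjusted p = 0.336 with an estimated correlation, and without H9 shDDX18#3 the camera adjusted p was 0.0619. E2F1 had an adjusted p of 0.055 without H9 shLuc and 0.0593 without HES2 shLuc, and BUB1 0.105 and 0.116.

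In camera at its preset correlation 3 metabolic lists moved down, though most genes of each list were not called. For comparison, 7.26% of all protein-coding genes tested fell. HMGCS1, an early enzyme of cholesterol synthesis, fell by 1.29 (adjusted p = 0.00539), with FDFT1 (-0.92) and FDPS (-0.78). Of 25 cholesterol synthesis genes 11 fell and 0 rose (13 and 0 adjusted over the list alone), with a median of -0.58 (camera adjusted p = 4.66e-07) and an adjusted p = 0.336 with an estimated correlation. Of 19 glycolysis genes 7 fell and 1 rose (7 and 1 adjusted over the list alone), with LDHA (-1.27), GPI (-0.94) and LDHB (-0.91) beside ALDOC, a median of -0.40 (camera adjusted p = 0.00147) and an adjusted p = 0.390 with an estimated correlation. Of 71 nuclear genes of oxidative phosphorylation 6 fell and 0 rose (5 and 0 adjusted over the list alone), among them COX7B (-1.01), ATP5MC2 (-0.71), COX5A (-0.65) and UQCRC2 (-0.63). That list's median was -0.26 (camera adjusted p = 7.88e-07), with an adjusted p = 0.336 with an estimated correlation. The 13 mitochondrially encoded mRNAs did not pass singly or as a list (median -0.16, camera adjusted p = 0.104), with MT-CO3 at -0.57 (adjusted p = 0.15) and MT-CO2 at -0.44 (adjusted p = 0.205). HMGCS1 had an adjusted p of 0.0653 without H9 shLuc and 0.0838 without HES2 shLuc, and LDHA stood at -0.77 without HES2 shLuc (adjusted p = 0.169). Mitochondrial mRNAs passed as a list without H9 shLuc (median -0.25, camera adjusted p = 0.0404), and their median was -0.064 without HES2 shLuc.

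Stress and chromatin lists gave mixed calls. DNAJB9, a chaperone of the endoplasmic reticulum, rose by 1.34 (adjusted p = 0.0101) with EDEM1 (0.95) and SEL1L (0.80), and HERPUD1 (0.91) was at the threshold (adjusted p = 0.0498). With these 4, of 20 unfolded protein response genes 4 rose and 0 fell, also adjusted over the list alone, but of 18 alternatives HERPUD1 missed the threshold in 11, SEL1L in 6, EDEM1 in 4 and DNAJB9 in 2. The list's median was 0.21 (camera adjusted p = 0.00864), with an adjusted p = 0.344 with an estimated correlation, and the median was 0.083 without HES2 shLuc (camera adjusted p = 0.164) and 0.44 without H9 shLuc. PPP1R15A (1.54) and ATF3 (1.11) rose, yet the integrated stress response as a list did not pass (4 of 29 rose, 3 fell, 5 and 3 adjusted over the list alone, median 0.02, camera adjusted p = 0.686). In the heterochromatin and lamina list LMNA, lamin A, rose by 1.62 (adjusted p = 0.00216) while LMNB1 (-1.04), UHRF1 (-1.49) and 4 others fell. Of its 31 genes 1 rose and 6 fell, also adjusted over the list alone, with a median of -0.30 (camera adjusted p = 0.0142) and an adjusted p = 0.496 with an estimated correlation, and without H9 shLuc the camera adjusted p was 0.166. Polycomb genes did not pass as a list (6 of 31 rose, 4 fell, 7 and 9 adjusted over the list alone, camera adjusted p = 0.338), with a median of -0.17 and a mean of 0.05 that differ in sign, though PHC2 (1.9) rose and CBX2 (-1.10) fell. Among 32 interferon response genes 0 rose and 5 fell, also adjusted over the list alone, including BST2 (-2.31) and IFITM3 (-0.85), with a list median of -0.08 (camera adjusted p = 0.187). Of 17 histone genes 2 rose, HIST1H4I (1.49) and HIST1H2BK (1.37), and 0 fell, also adjusted over the list alone, with a median of 0.54 (camera adjusted p = 0.0708). Without H9 shLuc LMNB1 stood at -0.64 (adjusted p = 0.326), and the lists of the integrated stress response (median -0.39, camera adjusted p = 0.0244), interferon response (-0.47, 0.0102) and histones (0.68, 0.0146) passed. Without HES2 shLuc HIST1H2BK stood at 0.89 (adjusted p = 0.235) and the integrated stress response passed in the other direction (median 0.44, camera adjusted p = 0.0176). The interferon list passed without H9 shDDX18#1 (0.0479) and histones without H9 shDDX18#3 (0.0256).

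Signaling lists did not pass as groups in the 6 libraries. CCN2, a matricellular protein, rose from 98.6 ± 18.0 (n = 2) to 382 ± 76.6 (n = 4), a log2 fold change of 1.93 with SE 0.14 (adjusted p = 0.000998), within a list of NODAL and TGF-beta responses where 4 of 17 rose and 3 fell (5 and 3 adjusted over the list alone, median 0.69, camera adjusted p = 0.0633). Of 17 FGF and ERK response genes 6 rose and 2 fell (7 and 2 adjusted over the list alone, median 0.58, camera adjusted p = 0.0816), with FOSL1 (1.53) up and ETV1 (-1.79) down. Of 16 WNT response genes 2 rose and 1 fell (also adjusted over the list alone, median 0.08, camera adjusted p = 0.516), with the stem cell receptor LGR5 (1.45) up and the mesoderm factor TBXT (-1.74) down. Of 469 zinc finger genes 10 rose and 10 fell (6 and 6 adjusted over the list alone, median -0.06, camera adjusted p = 0.402), such as ZNF654 (1.39) and ZNF589 (-1.71). In the lists of clustered protocadherins (33 genes, median 0.21, camera adjusted p = 0.232, fry adjusted p = 0.0397) and of genes of the two-cell or eight-cell-like state (6 genes, median 0.79, camera adjusted p = 0.0816) the genes with the smallest p did not pass, also adjusted over the list alone. They were PCDHA10 (0.76, adjusted p = 0.0813), PCDHGB4 (1.28, adjusted p = 0.0815), SLC34A2 (1.17, adjusted p = 0.186) and H3Y1 (1.70, adjusted p = 0.188). H3Y1 had 0 CPM in the H9 libraries and in HES2 shLuc, against 21.9 and 3.90 in HES2 shDDX18#1 and shDDX18#3. Its value was 3.40 without H9 shLuc and 0 without HES2 shLuc. SLC34A2 (1.61) and PCDHGB4 (1.55) passed without H9 shDDX18#3. The olfactory receptor list was drawn by symbol and includes the pseudogene OR7E12P, at -1.23 (adjusted p = 0.0594). For its 5 genes the median was 0.46 and the mean -0.03, with opposite signs (camera adjusted p = 0.997). Without H9 shLuc the lists of NODAL and TGF-beta (median 1.11, camera adjusted p = 0.0011), FGF and ERK (0.65, 0.00585) and WNT responses (0.52, 0.00228) and of the two-cell or eight-cell-like state (1.35, 0.00384) passed. FGF and ERK responses also passed without H9 shDDX18#1 (0.0428) and without H9 shDDX18#3 (0.0476), and NODAL and TGF-beta responses without H9 shDDX18#3 (0.0243). Without HES2 shLuc the medians were -0.05 for NODAL and TGF-beta responses, -0.34 for WNT responses and 0 for the two-cell or eight-cell-like state. Of the 36 lists, 21 passed camera at its preset correlation, 0 passed with an estimated correlation, and 10 passed fry, 9 of the 21 and clustered protocadherins.

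**Figure D2:**
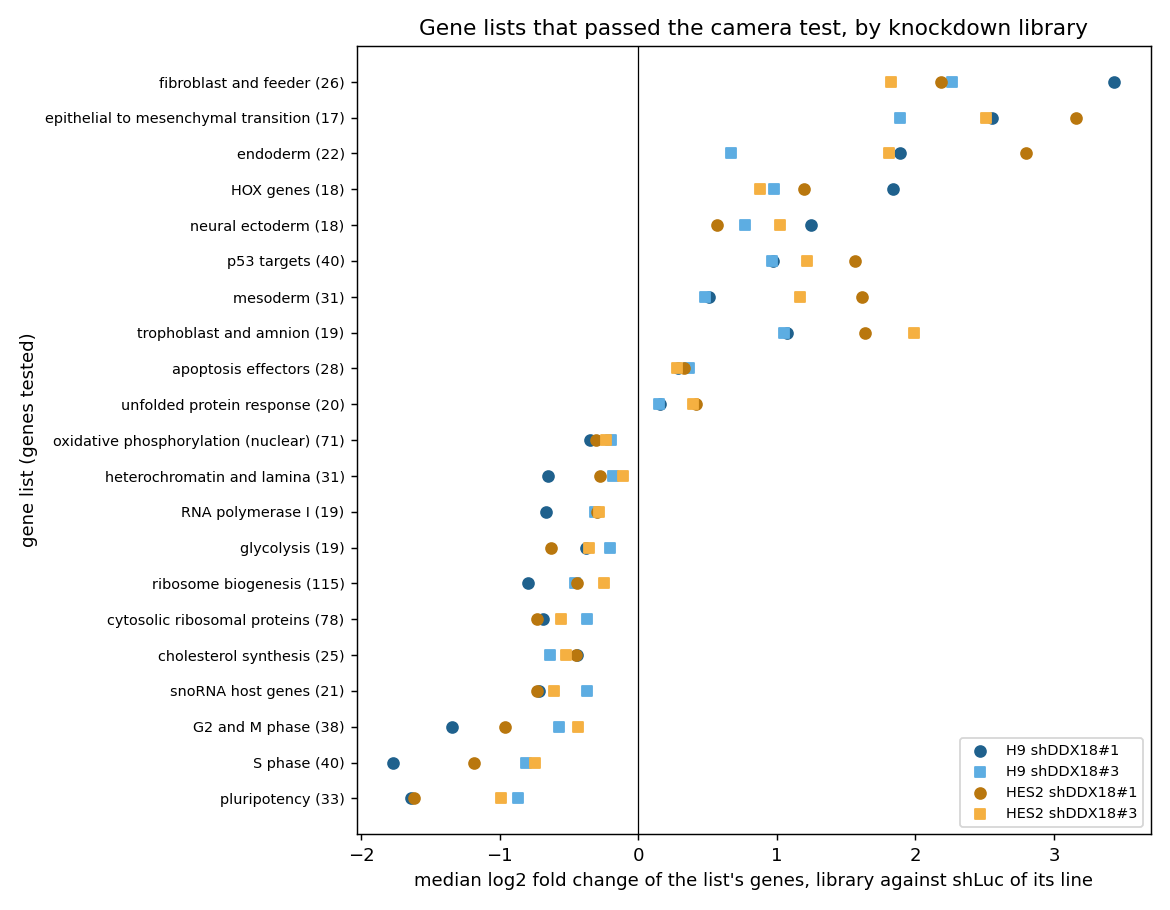
Median log2 fold change of each gene list that passed camera at its preset correlation (x axis), by list with the number of genes tested (y axis), with 1 point for each of the 4 knockdown libraries against the shLuc library of its line. The pluripotency medians lie between -1.64 and -0.86, and the fibroblast and feeder medians between 1.82 and 3.43.

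Taken one at a time, both hairpins lowered DDX18, and more genes were called for shDDX18#1. DDX18 changed by -2.47 with shDDX18#1 (limma adjusted p = 0.000257) and by -1.53 with shDDX18#3 (limma adjusted p = 0.0048). In limma 2559 genes rose and 2387 fell with shDDX18#1, and 1236 rose and 655 fell with shDDX18#3. The spread of fold changes over all genes was larger with shDDX18#1, at an SD of 1.01 in H9 and 0.93 in HES2 against 0.72 and 0.76 with shDDX18#3. Camera called 23 lists for shDDX18#1 and 20 for shDDX18#3, and 0 of either passed with an estimated correlation. Of the 36 lists, 16 passed fry for shDDX18#1 and 2 for shDDX18#3. Heterochromatin and lamina (camera adjusted p = 0.00218 and 0.0624), mitochondrial mRNAs (0.00829 and 0.347), NODAL and TGF-beta responses (0.0269 and 0.0832) and the two-cell or eight-cell-like list (0.0479 and 0.239) passed with shDDX18#1 and not with shDDX18#3, and apoptosis effectors (0.0768 and 0.0169) the other way round. The total of 1891 genes for shDDX18#3 was 23 without HES2 shDDX18#3 and 124 without H9 shDDX18#3. The total of 4946 for shDDX18#1 was 2428 without H9 shDDX18#1, 2947 without H9 shDDX18#3 and 2850 without HES2 shDDX18#3.

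Compared directly, the hairpins differed in how far the groups moved in camera at its preset correlation. Members of some lists also differed when adjusted over the list alone. With an estimated correlation 0 lists passed, in a test on 2 residual degrees of freedom that could hardly call any. In fry 0 lists passed. In limma 0 genes differed between shDDX18#3 and shDDX18#1 at an adjusted p under 0.05, with 2536 at an unadjusted p under 0.05, while edgeR called 31 and DESeq2 113. Without H9 shLuc 815 genes passed and without HES2 shLuc 817. SOX2 was higher with shDDX18#3 by 1.08 and the insulin-like growth factor binding protein IGFBP5 lower (-1.9), each with the smallest adjusted p reached, 0.0541. With that same adjusted p, the stathmin STMN3 (1.61), the membrane protein GPM6B (1.29), skeletal actin ACTA1 (1.74) and the synaptic protein UNC13A (1.94) were higher, and IGFBP3 (-1.43), heme oxygenase HMOX1 (-1.50), the protease CTSV (-1.12) and haptoglobin HP (-2.58) lower. DDX18 differed by 0.93 (adjusted p = 0.145). Camera called 17 lists, 10 higher and 7 lower with shDDX18#3, and 0 of them passed with an estimated correlation, where adjusted p ranged from 0.509 to 0.726. Several lists that fell under knockdown were less reduced with shDDX18#3: the median difference was 0.66 for G2 and M phase (camera adjusted p = 1.41e-22), 0.63 for S phase, 0.77 for pluripotency and 0.24 for ribosomal proteins. So it was for ribosome biogenesis (0.28), snoRNA host genes (0.32), glycolysis (0.30), heterochromatin and lamina (0.22) and RNA polymerase I (0.14), and mitochondrial mRNAs differed by 0.24. Of the other lists that fell, nuclear oxidative phosphorylation (0.10, camera adjusted p = 0.102) and cholesterol synthesis, which was lower with shDDX18#3 (-0.14, camera adjusted p = 0.0725), did not pass. Endoderm (-0.92), fibroblast and feeder (-0.85), mesenchymal genes (-0.73), HOX genes (-0.48), mesoderm (-0.37), the integrated stress response (-0.36) and p53 targets (-0.09) were lower with shDDX18#3. Adjusted over the list alone, 31 of 38 genes of G2 and M phase, 30 of 40 of S phase and 20 of 33 of pluripotency were higher with shDDX18#3, and 13 of 22 endoderm genes lower.

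Knockdown effects in the lines were positively correlated across genes. Mean fold changes in H9 and in HES2 correlated across 17768 genes with Pearson's r of 0.648 and Spearman's rho of 0.624, and 73.5% had the same sign, though genes are not independent replicates. Between lines, r was 0.641 for shDDX18#1 in both and 0.578 for shDDX18#3 in both, and 0.575 and 0.560 for the mixed pairs. The interaction test in limma called 0 genes, with 788 at an unadjusted p under 0.05 and a smallest adjusted p of 0.935, while edgeR called 0 and DESeq2 14. The genes with the smallest p had effects of opposite sign or unequal size, none passing. The prostate-associated RNA PCAT14 had an effect higher by 3.57 in HES2, cardiac actin ACTC1 by 2.73, the WNT antagonist DKK1 by 2.61, the BMP target ID1 by 2.36 and the growth factor IGF2 by 2.19. In the other direction the mitochondrial folate enzyme ALDH1L2 had an effect of -4.68 in HES2 relative to H9, the collagen COL22A1 -4.11, the peptidase ANPEP -3.10, the semaphorin SEMA7A -2.74 and the exchange factor RASGRF2 -2.26.

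**Figure D3:**
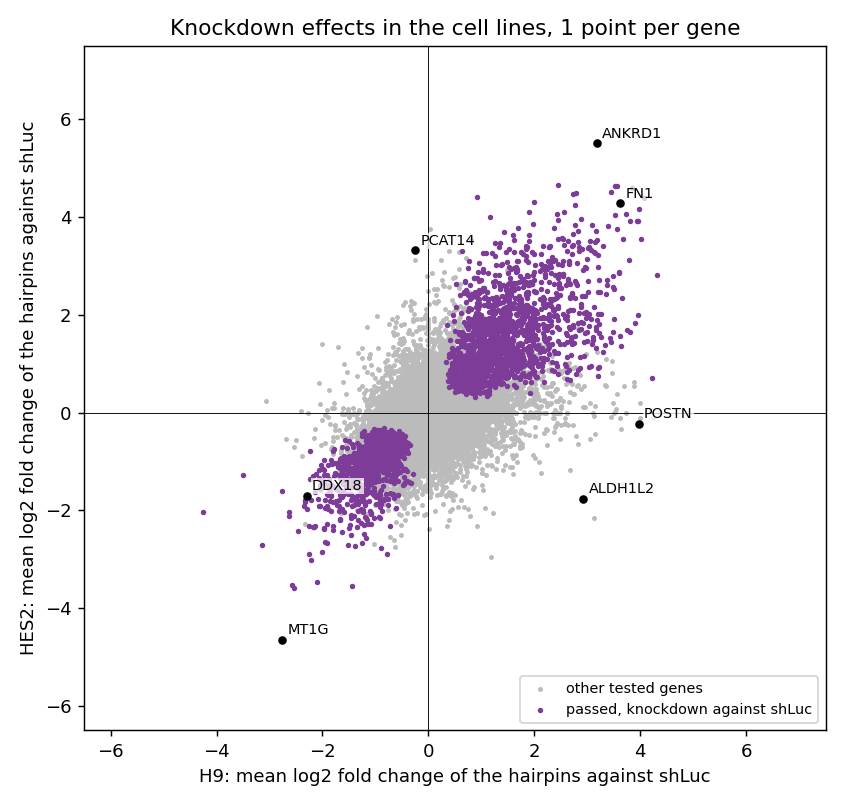
Mean log2 fold change of both hairpins against shLuc in H9 (x axis) and in HES2 (y axis), with 1 point per gene and the 2819 genes called for knockdown against shLuc in purple, other tested genes in gray and labelled genes in black. The values correlate across genes with Pearson's r of 0.648, and POSTN and ALDH1L2 lie far from the diagonal on the H9 side and PCAT14 on the HES2 side.

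Averaged over the arms, the lines differed in 963 genes, 255 higher and 708 lower in HES2 over 3 libraries against 3. Both knockdown libraries of each line enter this average, so the values are not differences between the shLuc libraries alone. HLA-B was at 8.72 CPM in HES2 shLuc and at 66.0 and 24.5 in HES2 shDDX18#1 and shDDX18#3. POSTN gained 1635 CPM over shLuc in H9 shDDX18#1 and 126 in H9 shDDX18#3. The imprinted RNA H19 differed by -8.14 with SE 0.39 (limma adjusted p = 2.77e-05), with 3366 reads over the H9 libraries and 2 over the HES2 libraries, a ratio of 2056 with a 95% counting interval of 569 to 16983. The matrix protein POSTN differed by -6.48 and the mitochondrial pseudogene MTND4P12, nearly identical to a mitochondrial gene and so of uncertain level, by -6.39. The proteasome chaperone PSMD5 had 0 reads in the HES2 libraries and was at least 214-fold lower there, against a floor of 3 reads over the group. Higher in HES2 were the endothelial protein PLVAP (4.64), LRRC61 (3.99), HLA-B (3.87), whose reads depend on how near the line's allele is to the reference, the dipeptidase DPEP1 (3.71) and THNSL2 (3.69), and for PLVAP, with 1 read over the H9 libraries, the ratio was 350 with a 95% counting interval of 62.4 to 13838. Camera called 14 lists, 6 higher and 8 lower in HES2. With an estimated correlation 0 of these passed, with adjusted p from 0.710 to 0.894, and 0 passed fry. Fibroblast and feeder markers were lower in HES2 in 20 of 26 cases (24 adjusted over the list alone), with a median of -1.68 (camera adjusted p = 1.73e-26), beside mesenchymal genes (-1.12), HOX genes (-0.68), mitochondrial mRNAs (-0.57), p53 targets (-0.47), neural ectoderm (-0.41), ribosomal proteins (-0.14) and nuclear oxidative phosphorylation (-0.09). Clustered protocadherins (0.63), epithelial junctions (0.37), S phase (0.28), zinc finger genes (0.21), heterochromatin and lamina (0.15) and ribosome biogenesis (0.11) were higher in HES2. The count of 963 was 95 without H9 shDDX18#3, 101 without HES2 shDDX18#3, 433 and 429 without shDDX18#1 of H9 and of HES2, and 2154 and 2146 without shLuc of H9 and of HES2.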

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

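The tests of fibroblast markers in this part, with the minimum increment of 20 CPM, were chosen only after the results had been seen, and the tests of the knockdown effect between lines were planned.

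Among 37 quantities (DDX18 and the 36 list medians) compared over the 4 knockdown libraries, 1 had a library far from the others, where about 1 in 20 would by chance. The median fold change of the RNA polymerase I list was -0.66 in H9 shDDX18#1 against -0.31, -0.30 and -0.28 in the other libraries, a gap of 0.92 of the whole range.

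For 15 lists the knockdown effect differed between the lines in camera on the interaction term. With an estimated correlation 0 of these differences passed, with adjusted p from 0.677 to 0.875, and 0 passed fry. The median difference, HES2 minus H9, was -0.72 for the integrated stress response, with effects of 0.44 in H9 and -0.39 in HES2. It was 1.18 for WNT responses, with effects of -0.34 in H9 and 0.52 in HES2, and 0.54 for p53 targets, which rose in both lines (0.96 and 1.42). Effects were more positive in HES2 for ribosome biogenesis (0.28), mesoderm (0.43), S phase (0.40), NODAL and TGF-beta responses (0.35), the two-cell or eight-cell-like state (1.45), FGF and ERK responses (0.29), trophoblast and amnion (1.18), heterochromatin and lamina (0.19), mesenchymal genes (0.34), and G2 and M phase (0.22). They were more negative in HES2 for the interferon response (-0.41) and the fibroblast and feeder list (-0.64). The effect in each line is measured against its 1 shLuc library, so these differences rest on 1 control library per line. Without either of these libraries the difference between lines cannot be estimated.

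The rise of fibroblast and matrix genes was weighed against RNA of feeder or other fibroblast cells in the knockdown libraries. The feeders were mouse cells and the reads were handled against hg19. Feeder RNA would therefore count here only where mouse reads match human genes, and how many do was not tested. A single source shared by both lines would bring its transcripts in 1 ratio, but of 26 markers with an increment of at least 20 CPM in H9 shDDX18#1 only 9 had an increment in HES2 shDDX18#1 within 2-fold of the median ratio of 0.134. POSTN gained 1635 CPM in the first and 0.044 in the second, LGALS1 320 and 2.34, and MMP2 452 and 458, which argues against 1 common source. Within a line, 19 of 26 markers were within 2-fold of 0.309 between the H9 knockdown libraries and 15 of 20 were within 2-fold of 0.815 between those of HES2, with COL1A1 gaining 17699 CPM in H9 shDDX18#1. A response of the stem cells themselves to either hairpin, measured against the same shLuc library, would also bring ratios close together, so a separate source in each line and a change of the cells after DDX18 depletion, which was not tested, both stay open, and 21 of the 26 markers were already at 3 CPM or more in both shLuc libraries.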

How the results depend on the processing

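The number of calls depends on the model and on single libraries. In 0 cases did a gene named by the rule, or a list that passed camera for knockdown against shLuc in the 6 libraries, change direction under the alternatives run for it. Genes named for the closing section alone, and lists in the other comparisons, were not run under the alternatives, apart from the estimated correlation and fry for those lists. Changing pseudocount, filter or scaling left the comparison counts within 1.5 times, except 18 genes between hairpins after quantile normalization. Without the intensity trend 886 genes rose and 342 fell, 2810 changed with shDDX18#1, 227 with shDDX18#3 and 184 between lines. Without the cell line block the values were 790, 409, 2126, 18 and 36. DESeq2 gave 2873 for shDDX18#1, 1183 for shDDX18#3, 113 between hairpins and 14 for the effect between lines, edgeR gave 31 between hairpins and a robust prior 43. A fold threshold of 2 left 461 falls. Of the 21 lists 0 passed with an estimated correlation and 9 passed fry, which gave 10 with clustered protocadherins. NODAL and TGF-beta responses passed after quantile normalization (camera adjusted p = 0.0305) and with edgeR (0.0216), FGF and ERK responses after quantile normalization (0.0448), and histones without the trend (0.0498). The median of olfactory receptors was 0.75 at a pseudocount of 0.25 and 0.46 without the trend, with the opposite camera direction. DCX passed at a pseudocount of 4, after quantile normalization, without the trend and with edgeR. OR7E12P passed at a pseudocount of 4 and after quantile normalization, and MT-CO3 with DESeq2. For these the cause was not tested.

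Leaving out 1 library at a time gave 185 to 1986 rises and 7 to 1604 falls, 2428 to 4657 genes for shDDX18#1, 23 to 2232 for shDDX18#3, 0 to 817 between hairpins and 95 to 2154 between lines. DDX18 lay between -2.30 and -1.69, the correlation between lines between 0.599 and 0.648, and 20 to 30 lists passed. The camera direction changed for the integrated stress response (median -0.39 to 0.44), WNT responses (-0.34 to 0.52) and olfactory receptors (0.20 to 0.44, with no change of sign). The median alone also crossed 0 for the interferon response (-0.47 to 0.12), epithelial junctions (-0.08 to 0.27) and NODAL and TGF-beta responses (-0.05 to 1.11). Each end of the ranges of these lists is the median effect of 1 line, fitted without the shLuc library of the other line. Why the lines differ was not tested. With 6 libraries, each of these fits has fewer samples by construction, and without a shLuc library the effect between lines cannot be estimated. The fit of that effect without the block was likewise not run.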

Other observations

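The tests of POU5F1, of the metallothioneins and of YAP and SRF targets, with the lists they use, were chosen only after values of these genes had been seen, and those of ribosomal protein transcripts were chosen before their results.

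Ribosomal protein mRNAs fell with a median of -0.58. Genes matched in exon length and level had a median of -0.079, and 0 of 10000 random matched lists had a median as low, the lowest being -0.44. Exon length here was the union of all annotated exons of a gene, which can exceed the length of its mRNA. A bias against short mRNAs therefore stays open. The random lists also hold unrelated genes, whereas the members of this list move together (estimated correlation 0.60). Relative to the median of all genes the list stood at -0.56, and at -0.45 after quantile normalization. The other scalings tried use 1 factor per library, which shifts the list and all genes alike. They could not have changed this value, so they decide nothing about scaling. RNA quality and the number of feeder cells were not tested, and an effect of DDX18 depletion on these transcripts is a hypothesis.

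POU5F1 lay between 0.322 and 3.58 CPM in all 6 libraries of stem cells. Of 174 annotated protein-coding genes between TRIM27 and KIFC1, the region around it, 11 have a value in the deposited table, or 6.32% against 70.8% elsewhere. This is consistent with reads of that region having been lost to alternate copies in the reference. The copies POU5F1B, POU5F1P3 and POU5F1P4 summed to 267 CPM in H9 shLuc and 263 in HES2 shLuc, and to between 59.5 and 154 in the knockdown libraries, so reads of POU5F1 may have been placed there. HLA genes lie in the same region, and values for them carry the same doubt.

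ANKRD1, NPPB and ACTA2 respond to YAP and to SRF, transcriptional regulators linked to tension and the actin skeleton. A list of 43 other targets of these factors, without members of the fibroblast and mesenchymal lists and with IGFBP3 taken off after a first test, had 25 genes that rose and 0 that fell (30 and 0 adjusted over the list alone), with a median of 0.90 (camera adjusted p = 7.40e-15) and an adjusted p = 0.0875 with an estimated correlation. Its median was 1.01 and 0.91 in H9 and 1.00 and 0.97 in HES2, with TGFB2 at 3.60, CCN2 at 1.93, CRIM1 at 1.58 and SRF itself at -0.36 (adjusted p = 0.228). Members that were not called included FHL2 (0.20), CNN1 (0.11), ACTB (0.11) and VCL (0.06). The list mixes targets of YAP with targets of SRF, so it cannot tell which of them rose. A candidate explanation is a rise of YAP or SRF activity in the knockdown cells, and fibroblast RNA could raise some of these genes too.

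Beyond MT1G, MT1H and MT1E, 3 other metallothionein genes had a mean of at least 3 CPM, and 2 of them passed, MT1X (-1.93) and MT1F (-1.92). MT2A did not pass (-1.14, adjusted p = 0.109) and was higher in H9 shDDX18#1 by 0.38. A fall shared by much of the family is a candidate explanation, with a metal or glucocorticoid cue left untested.

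For HES2 against H9, 963 genes passed, and the highest count among the other splits of the 6 libraries into 3 and 3 was 0, so 1 of 10 splits gave as many, and 10 splits are too few for a share under 0.05.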
